A study of Mus musculus with 14 samples.

How the data were processed

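RNA was extracted from mouse embryonic fibroblasts with TRIzol and messenger RNA was captured on oligo(dT) beads, per the labels' protocols. Fragments of 50 to 100 nucleotides were excised from a gel, dephosphorylated, tailed with poly(A), ligated to an adapter, copied to cDNA and amplified by PCR with barcoded primers, per the labels' protocols. Reads carried no molecular identifiers as far as the labels state. The submitters' processing notes name bcl2fastq 2.20.0.422, cutadapt 2.8, Bowtie 1.2.3 and STAR 2.7.10a, and the mouse assembly GRCm39, without stating the role or order of each. The counting tool, the strand setting and the annotation are not given in the sources used here. Each library was deposited by the authors as a table of counts, whole numbers per Ensembl transcript, not normalized; although the tables are named as CPM, the values are whole numbers whose totals differ between libraries, from 25697 to 165747. All 14 tables list the same 1399 transcripts, and the smallest value is 1, so the transcripts appear to have been kept for having a count in every library. A transcript absent from 1 library is therefore outside these tables, totals are not depths, and falls to 0 cannot be seen. Because counts were used, the precision of a value follows from its count: the median count per transcript lay between 3 and 16 in the first experiment and between 22 and 61 in the second.

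Transcripts were named by their identifiers from GENCODE mouse release 21, which is on GRCm38; names and sequences were taken from it and no coordinates were used, because the counts were made on GRCm39. A symbol was found for 1385 transcripts and none for 14. Samples were grouped by their labels into 7 groups of 2. The test, the samples, the 28 gene lists and the rule for named genes were chosen before the data were examined. That plan named limma on log2(CPM + 1) for CPM values, and edgeR's quasi-likelihood test if the values were counts; the latter was used, and limma is given as an alternative. edgeR 4.0.16 in R 4.3.3 fitted all 14 libraries with 7 group means, which leaves 7 residual degrees of freedom, after scaling by the trimmed mean of M values (TMM), and p-values were adjusted over 1399 transcripts by the Benjamini-Hochberg method with a threshold of 0.05. Each adjusted p printed for a transcript is from this test unless another tool is named, and tests were two-sided. Log2 CPM values, used for the list tests and the correlations, were computed with a prior count of 2. The fitted log2 fold changes kept edgeR's default prior count. 7 comparisons and 3 differences between effects were tested. Lists with at least 3 measured members, 15 of 28, were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, and again with an estimated correlation; adjusted p for lists is over the lists of a comparison. The preset correlation gave 22 list calls in the 7 comparisons, and 35 with the 3 differences counted. None of the 35 held with an estimated correlation.

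Named genes were, for each comparison, the 8 highest and 8 lowest log2 fold changes among transcripts past the threshold with a mean of at least 10 CPM in a group and libraries that do not overlap between groups, 5 and 5 for the differences, and the 5 highest and 5 lowest moderated statistics where none passed. Up to 4 members of each list with the smallest p were added, and a set of stress genes of which Atf4 alone was measured. Some of these named genes are not reported here. A few transcripts named outside this rule, such as the 3 with the highest counts, the list members of fewer than 3, and Lox in rescue against knockdown, were chosen after their values were seen. Tracking transcripts were defined after the data were seen, as those whose ratio to the 3 dominant transcripts in NT over the same ratio in NT2 was above 2 times its median, which gave 341. The dominant transcripts cancel out of this rule, so it picks transcripts by their count in NT relative to NT2 alone. Leaving the tracking transcripts out, a second definition from the rescue libraries that left 1127, and a minimum mean count of 20 that left 897 were added as alternatives. Correlations expected from shared control libraries came from 100 simulations of groups without any difference. The fit was tested on simulated data with the means and totals of these libraries and 50 transcripts per fold size. Each simulation gave the spread of 1 experiment, that of the comparison, to all 14 libraries. The unequal spreads that the real fit pools were thus not simulated, and the rates below hold for equal spreads only. For knockdown against NT2 it called 98% of those raised by 2 on the log2 scale, 74% of those raised by 1, 62% of those lowered by 1 and 80% of those lowered by 2, and 6 of 1199 unchanged ones; for cysteine starvation against NT it called 56%, 4%, 4% and 14%, and 0 of 1199. The list test found 1 of 1 shifted lists and 0 of 15 unshifted ones on the simulated knockdown comparison. The run was set to stop if the shifted list was missed. Genes varied independently in it, so it cannot tell how the preset correlation performs where genes vary together. Alternatives tried were DESeq2 1.42.0, median-of-ratios and quantile scaling, limma with several pseudocounts or without trend, libraries of 1 experiment only, the other or both untreated groups as control, the replicate number as a block, and each library left out in turn. When a library is left out its group has 1 library, which is assumed to vary like the other groups. Reads shared between near-identical copies were not resolved, so ribosomal proteins, Hsp90aa1 and Hsp90ab1, Hspa8, Eef1a1, Fth1 and Gapdh are uncertain.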

Results

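The lysosomal membrane protein cystinosin, encoded by Ctns, carries cystine out of the lysosome, and cysteamine is a drug that removes lysosomal cystine by converting it to forms that leave by another transporter. The series concerns how lysosomal cystine affects sensitivity to ferroptosis, an iron-dependent death driven by lipid peroxidation, and how the nucleus responds to cysteine. Polyadenylated RNA was sequenced from mouse embryonic fibroblasts (MEFs), a connective tissue cell type, in 14 libraries that formed 7 groups of 2. The untreated group NT, cysteine starvation and full amino acid starvation made up the first experiment (6 libraries). A further untreated group, NT2, stood with cysteamine treatment, knockdown of Ctns by a short hairpin RNA (CTNS knockdown), and the same knockdown with a CTNS plasmid (rescue) in the second experiment (8 libraries). The labels did not state which untreated group belonged to which treatments, so this assignment, NT for the starvations and NT2 for the others, was read from the naming and is an assumption. They also did not state whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. That spread was estimated over all 14 libraries, so a p-value of 1 experiment also draws on the spread of the other. The spreads were unequal. Chi-square per degree of freedom within a group, which counting noise alone puts near 1, was 2.54 to 4.55 in the first experiment and 1.55 to 1.95 in the second.

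Each library was a table of whole-number counts for the same 1399 transcripts, every one with a count of at least 1 in every library. Totals over these transcripts were 33990 and 25697 in NT, 51224 and 46925 in cysteine starvation, and 30784 and 44946 in full amino acid starvation. In the second experiment they were 165747 and 132998 in NT2, 135829 and 162055 with cysteamine, 98481 and 79630 in CTNS knockdown, and 87972 and 64530 in rescue. The totals cover the listed transcripts only and are not sequencing depths, and the first experiment was counted more thinly than the second. Below, levels are CPM scaled by the trimmed mean of M values with their SD over 2 libraries, and log2 fold changes carry their standard error (SE). Where a group in 1 of the 7 comparisons of groups held 3 counts or fewer of a named gene, a ratio of counts is given with its exact 95% interval, which covers counting error alone; differences between effects carry the SE only.

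The libraries differed in makeup as well as in size. The 3 transcripts with the highest total counts, Luc7l2 (ENSMUST00000161538), Pigl (ENSMUST00000014389) and Pglyrp3 (ENSMUST00000047660), held 45.3% ± 13.1 of the counts in NT and 3.39% ± 0.14 in NT2 (SD, n = 2 each). They held 26.8% ± 8.91 in cysteine starvation and 41.9% ± 1.04 in full amino acid starvation. They held 7.85% ± 0.183 with cysteamine, 15.9% ± 0.0954 in the knockdown and 19.8% ± 1.73 in the rescue. A class of 341 transcripts, these 3 included, is called tracking transcripts here. It was defined after the data were seen, by a high count in NT relative to NT2. The counts of the 3 cancel out of that rule, so moving with them was not a criterion. Members need not follow the 3 in every group. Since NT and NT2 entered the definition, falls against NT and rises against NT2 are favoured by the selection. The same holds for a positive difference of an effect against NT2 minus an effect against NT. In the knockdown against NT2 167 were called higher and 0 lower, while Postn, a member, stood at -1.47 (adjusted p = 0.0862). The class included Ctrb1, a pancreatic protease gene, Cdh1, an epithelial cadherin gene, and Ttn, a muscle gene. The class took 75.3% ± 16.2 of the counts in NT, 47.6% ± 14.05 in cysteine starvation and 80.8% ± 2.88 in full amino acid starvation. In the second experiment it took 9.49% ± 0.145 in NT2, 16.8% ± 0.807 with cysteamine, 32.3% ± 0.495 in the knockdown and 40.6% ± 1.71 in the rescue. Spearman correlations across transcripts between the libraries of a group, which are not independent observations, were 0.556 in NT, 0.830 in cysteine starvation and 0.686 in full amino acid starvation. They were 0.976 in NT2, 0.970 with cysteamine, 0.936 in the knockdown and 0.912 in the rescue. No pair differed by less than counting noise, so all 14 libraries were counted. Results for tracking transcripts are set apart from those for the other 1058 in what follows.

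**Figure D1:**
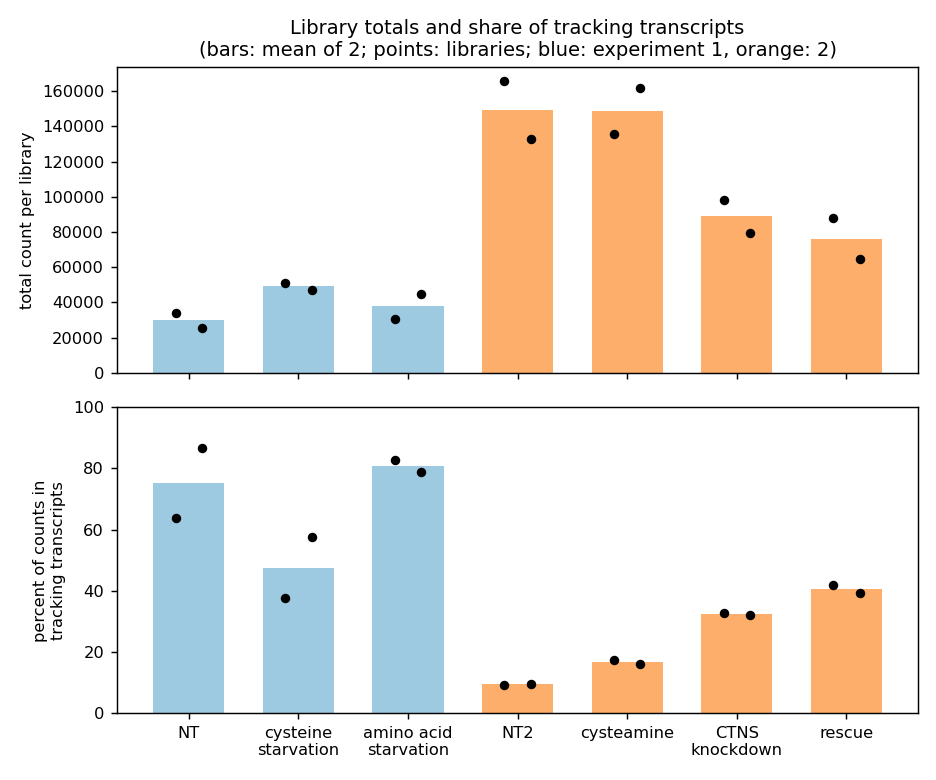
Total count of each library (top) and percent of its counts in tracking transcripts (bottom), with points for libraries, bars for the mean of 2, blue for the first experiment and orange for the second. Tracking transcripts took 75.3% of the counts in NT and 9.49% in NT2, the 2 untreated groups, from which the class was defined.

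The comparison of cysteine starvation with NT asks what changes in MEFs when cysteine alone is withheld. Genes for the uptake, synthesis and charging of amino acids lay higher in starved cells as groups with a preset correlation between genes, and not with an estimated one. Slc3a2, the heavy chain shared by several amino acid exchangers including the cystine importer, measured 572 ± 172 CPM in starved and 116 ± 113 CPM in untreated cells (7.59-fold, 95% interval 2.47 to 37.8). Mthfd2, a mitochondrial folate enzyme, measured 486 ± 56.6 against 84.8 ± 18.6 CPM (6.07-fold, 95% interval 1.96 to 30.5). The alanyl-tRNA synthetase gene Aars measured 999 ± 174 against 370.3 ± 169 CPM (log2 fold change 1.66 ± 0.38). No single transcript passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, so 0 were called, and the smallest adjusted p was 0.057. Of the transcripts 230 had an unadjusted p under 0.05, DESeq2 called 11 higher and 49 lower, and limma 5 higher and 0 lower. With NT2 or both untreated groups as the control edgeR did call transcripts, as given in the part on processing.

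By list, none of the 4 amino acid transporters measured passed over all transcripts and 1 rose when adjusted over the list alone, with all 4 above 0 (adjusted p = 0.0194, and adjusted p = 0.139 with an estimated correlation). Besides Slc3a2 these were the glutamine and neutral amino acid carriers Slc38a2 (1.17 ± 0.48), Slc1a5 (1.47 ± 0.85; 2.84-fold, 95% interval 0.661 to 25.6) and Slc38a1 (0.51 ± 0.46). Of 5 amino acid synthesis genes, 0 passed over all transcripts and 4 rose when adjusted over the list alone (adjusted p = 0.0131, and adjusted p = 0.139 with an estimated correlation). Shmt2, the mitochondrial serine hydroxymethyltransferase, stood at 1.74 ± 0.50, the proline synthesis gene Aldh18a1 at 1.25 ± 0.51 and Phgdh, which opens serine synthesis, at 1.01 ± 0.43. The rise of Aldh18a1 rested on 1 library, as it measured 348 ± 340 CPM in NT. Its log2 fold change was -0.035 without NT replicate 1 and 2.40 without NT replicate 2. Of 8 aminoacyl-tRNA synthetases, 7 were above 0, 0 passed over all and 2 rose when adjusted over the list alone (adjusted p = 0.00423, and adjusted p = 0.139 with an estimated correlation). Lars stood at 2.44 ± 0.58, Nars at 0.998 ± 0.49 and Vars at 0.86 ± 0.40. Atf4, the transcription factor that drives many of these genes during amino acid shortage, measured 949 ± 315 against 429 ± 52.1 CPM (1.14 ± 0.37, adjusted p = 0.123). Over the 17 transporter, synthesis and synthetase genes the median log2 fold change was 1.11, and 15 were above 0. The transporter result passed neither without NT replicate 1 (adjusted p = 0.117) nor without cysteine starvation replicate 1 (0.118). The synthesis result passed neither without NT replicate 1 (0.0864) nor without cysteine starvation replicate 2 (0.0685). With NT2 in place of NT as the control none of the 3 lists passed (adjusted p = 0.262 for transporters, 0.302 for synthesis and 0.262 for synthetases), and with both untreated groups as the control all did (0.00608, 0.00608 and 0.00126). The transporter list did not pass among transcripts with a mean count of 20 or more (0.137).

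Further lists passed with the preset correlation. Of 40 ribosomal protein and elongation factor genes, 35 were above 0 and 0 passed, over all or adjusted over the list alone (adjusted p = 1.80e-06, and adjusted p = 0.335 with an estimated correlation). Rpl14 stood at 1.37 ± 0.47 and Rpl7a at 0.82 ± 0.33, and reads of this family are shared with many pseudogenes, so its values are uncertain. Of 20 extracellular matrix genes 16 were above 0, 0 passed over all and 1 rose when adjusted over the list alone (adjusted p = 0.0107, and adjusted p = 0.335 with an estimated correlation). The collagen crosslinking enzyme gene Lox stood at 1.05 ± 0.29, the fibrillar collagen gene Col5a2 at 0.89 ± 0.30 and the fibronectin gene Fn1 at 0.86 ± 0.35. Of 11 contractile genes and YAP targets 9 were above 0, 0 passed over all and 3 rose and 1 fell when adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.335 with an estimated correlation; adjusted p = 0.182 without the tracking transcripts). Among them were Ccn1 (1.60 ± 0.43), the smooth muscle actin gene Acta2 (1.51 ± 0.42) and, in the other direction, the tropomyosin gene Tpm2 (-1.50 ± 0.51). The matrix and contractile results did not pass without NT replicate 2 (adjusted p = 0.187 and 0.421) or without cysteine starvation replicate 2 (0.087 and 0.0685). With NT2 as the control the ribosomal median turned to -0.27 (adjusted p = 0.0262) and the contractile one to -0.028, and the matrix list did not pass (0.982). With both untreated groups as the control the ribosomal (0.108) and contractile (0.1) lists did not pass. Among transcripts with a mean count of 20 or more the matrix (0.107) and contractile (0.215) lists did not pass.

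The highest moderated statistics belonged to Ptgs1, a prostaglandin synthase gene (2.18 ± 0.50, adjusted p = 0.074), and the angiogenic factor gene Vegfa (2.02 ± 0.47), with Aars, Slc3a2 and Lars. The 5 lowest were the tracking transcripts Nbeal2 (-1.95 ± 0.35), Srpk3 (-1.44 ± 0.28), Phc3 (-1.43 ± 0.29), Cubn (-2.19 ± 0.46) and Rbm15b (-1.60 ± 0.36). The tracking transcripts had a median log2 fold change of -1.16 and the others 0.21. NT entered the definition of the class, which favours such a fall. Without NT replicate 1 the number called was 112, and without cysteine starvation replicate 2 it was 65, against 0 with all libraries. On simulated counts with the means of these libraries, 56% of 50 transcripts raised by 2 on the log2 scale were called and 14% of 50 lowered by 2. These counts took the spread of the first experiment in every library, unlike the real ones.

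Full amino acid starvation against NT asks the same of the loss of all amino acids. The aminoacyl-tRNA synthetases were the only list of 15 past the threshold. Of its members 6 of 8 were above 0, 0 passed over all transcripts, and 1 rose when adjusted over the list alone (adjusted p = 0.044, and adjusted p = 0.501 with an estimated correlation). Aars measured 889.8 ± 296 CPM in starved cells against 370.3 ± 169 CPM in NT (1.53 ± 0.43). Lars stood at 1.60 ± 0.75, Nars at 1.22 ± 0.54 and Eprs, a tracking transcript, at 1.03 ± 0.37. Slc38a2, an amino acid importer that is induced by amino acid shortage, stood at 1.73 ± 0.51 (adjusted p = 0.36). Aldh18a1 stood at 1.72 ± 0.54 and Atf4 at 0.021 ± 0.49. On 3 counts each in NT, the intervals of Slc3a2 (3.06-fold, 95% interval 0.762 to 17.5) and Mthfd2 (2.72-fold, 95% interval 0.652 to 15.9) include 1. The median of the 17 amino acid genes was 1.03, with 13 above 0. The synthetase result did not pass without NT replicate 2 (adjusted p = 0.208) or without full amino acid starvation replicate 2 (0.217), nor with NT2 (0.696) or both untreated groups (0.276) as the control.

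No transcript was called by edgeR's quasi-likelihood test, where 0 passed and the smallest adjusted p was 0.319. Of the transcripts 109 had an unadjusted p under 0.05, DESeq2 called 0, and limma called 8 higher and 5 lower. With NT2 or both untreated groups as the control edgeR did call transcripts, as given in the part on processing. The highest moderated statistics were those of Myrfl (1.71 ± 0.40), Atp13a3 (1.42 ± 0.34), Abca12 (1.56 ± 0.41) and Bcor (1.25 ± 0.33), all tracking, and Brwd1 (1.99 ± 0.49). The lowest were those of Rrbp1, a ribosome-binding protein gene of the endoplasmic reticulum (-1.61 ± 0.36), Ppm1g (-1.64 ± 0.48), the nucleolin gene Ncl (-1.15 ± 0.35), and Mroh6 (-1.98 ± 0.62) and 8030462N17Rik (-2.03 ± 0.67), the last pair tracking. The basement membrane collagen gene Col4a2 stood at 1.34 ± 0.37 and the matrix gene Postn, tracking, at 2.002 ± 0.67. All 7 heat shock genes were below 0 (adjusted p = 0.0649 for the list), Hspa8 at -0.76 ± 0.46 and Hsph1 at -0.68 ± 0.45. Among ribosomal protein genes 29 of 40 were above 0 (adjusted p = 0.0649), Rpl27 at 1.48 ± 0.48; neither list passed. The count was 20 without NT replicate 2 and 16 without full amino acid starvation replicate 2.

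**Figure D2:**
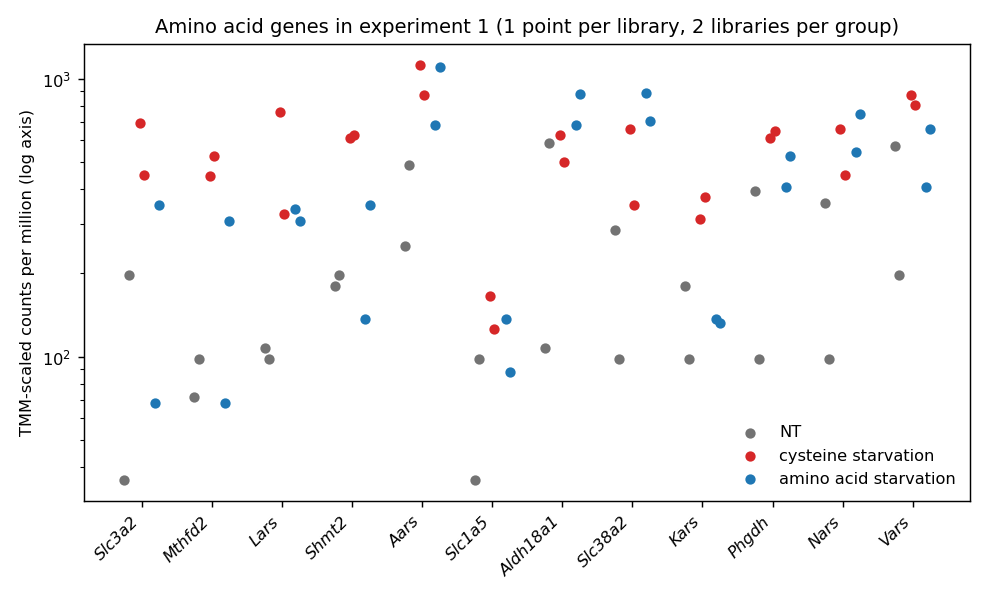
CPM on a log axis for 12 amino acid transporter, synthesis and aminoacyl-tRNA synthetase genes, with a point for each library of NT (grey), cysteine starvation (red) and full amino acid starvation (blue). Slc3a2 averaged 572 CPM in cysteine starvation and 116 CPM in NT, and the libraries of NT lie far apart for several genes.

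Cysteine starvation set directly against full amino acid starvation asks which genes separate the loss of cysteine from the loss of all amino acids. Higher with cysteine starvation were Nop56, a nucleolar factor of ribosome assembly (659.5 ± 47.6 against 100.0 ± 45.1 CPM; log2 fold change 2.63 ± 0.59), Fth1, the ferritin heavy chain that stores iron (1.84 ± 0.45), and Vegfa (1.80 ± 0.45). Higher too were the chaperonin gene Cct4 (1.91 ± 0.57) and the chromatin remodeller gene Smarca4 (1.96 ± 0.54). Lower were mainly tracking transcripts, led by Ctrb1 (79.1 ± 65.2 against 1054 ± 624 CPM; -3.97 ± 0.64). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 36 transcripts were higher and 174 lower, and 162 of the lower ones and 1 of the higher ones were tracking. With the tracking transcripts left out and the rest scaled and tested again, 4 were higher and 14 lower.

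Among the largest changes, Myo9b (3.85-fold, 95% interval 1.2 to 19.7) and the anchoring protein gene Akap9 (1.79 ± 0.58, adjusted p = 0.0494) also rose, as did Mroh6, tracking (1.92 ± 0.56). The lowest besides Ctrb1 were Gsdme, a gasdermin gene (11.6-fold lower, 95% interval 3.2 to 63.7), and Socs1 (10.7-fold lower, 95% interval 2.9 to 59.3), both tracking. They were followed by Slc17a9 (-3.10 ± 0.66), Nme9 (-2.99 ± 0.59), Kif24 (-2.94 ± 0.59) and Cdh1 (-2.81 ± 0.84, adjusted p = 0.0366), all tracking. The clock gene Per3 was among the 8 lowest without being tracking (9.4-fold lower, 95% interval 1.79 to 92.7). The skeletal muscle marker Ttn, also tracking, fell (-2.05 ± 0.42, adjusted p = 0.00511). Of 11 contractile genes and YAP targets 2 rose, Acta2 (1.33 ± 0.40) and Tagln (1.66 ± 0.54), and 10 were above 0 (2 rose when adjusted over the list alone; adjusted p = 0.0477, and adjusted p = 0.46 with an estimated correlation; adjusted p = 0.221 without the tracking transcripts). No other list of the 15 passed. Within them the basement membrane collagen gene Col4a1 (0.996 ± 0.31), the protease inhibitor gene Timp3 (1.17 ± 0.33), the endoplasmic reticulum chaperone gene Hspa5 (1.19 ± 0.37), and the mitochondrially encoded mt-Nd1 (1.46 ± 0.44) and mt-Co2 (1.21 ± 0.38) rose. P4ha1 (-1.92 ± 0.38), Postn (-2.41 ± 0.56) and Eprs (-1.07 ± 0.32), all tracking, fell. Atf4 stood at 1.11 ± 0.37 (adjusted p = 0.0509) and Slc3a2 at 1.30 ± 0.51 (adjusted p = 0.103).

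The calls rested on few libraries. The total of 210 fell to 18 without cysteine starvation replicate 1 and 64 without full amino acid starvation replicate 1. It was 193 without cysteine starvation replicate 2 and 190 without full amino acid starvation replicate 2, and was 87 when only the first experiment was fitted. Of 26 called named genes, 25, 21, 9 and 12 were not called in those leave-out fits, and 0 were called in all of them. The share of calls that were higher was 17.1%, 34.3% by limma and 48.4% after quantile normalization, and the median over all transcripts moved from 0.05 to 0.16 with the last. The contractile list did not pass without full amino acid starvation replicate 1 (adjusted p = 0.346) or cysteine starvation replicate 2 (0.0814), on log2 CPM values by limma (0.0549), or with a mean count of 20 or more (0.3).

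Cysteamine against NT2 asks what depletion of lysosomal cystine by a drug changes. The 3 measured genes of the list for the oxidative stress factor NRF2 rose, and 7 of 8 endoplasmic reticulum chaperone genes and 5 of 20 matrix genes fell. No list call held with an estimated correlation. The peroxiredoxin gene Prdx1 (662 ± 38.4 against 308 ± 9.73 CPM; log2 fold change 1.11 ± 0.18), the glutathione conjugate exporter gene Abcc1 (1.35 ± 0.26) and Fth1 (1.18 ± 0.22) all rose. They were the measured targets of the oxidative stress factor NRF2 (3 of 3 over all transcripts and 3 adjusted over the list alone; adjusted p = 4.37e-04, and adjusted p = 0.0969 with an estimated correlation). Sqstm1, the autophagy receptor p62, rose too (760.1 ± 49.7 against 324 ± 61.8 CPM; 1.21 ± 0.25, adjusted p = 0.00518). Of 8 endoplasmic reticulum chaperones 7 fell (7 adjusted over the list alone; adjusted p = 3.07e-06, and adjusted p = 0.102 with an estimated correlation). Among them were Pdia4 (187 ± 30.8 against 466 ± 32.2 CPM; -1.30 ± 0.21), Calr (-1.18 ± 0.25), Pdia6 (-0.98 ± 0.20) and Hyou1 (-0.94 ± 0.19).

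Of 20 extracellular matrix genes 5 fell and 0 rose over all transcripts, 11 fell and 1 rose when adjusted over the list alone, and 18 were below 0 (adjusted p = 2.88e-07, and adjusted p = 0.102 with an estimated correlation). Col1a2, a chain of type I collagen, fell (-1.94 ± 0.33), with the type VI collagen genes Col6a2 (-1.40 ± 0.21) and Col6a1 (-1.17 ± 0.20) and with Lox (-0.82 ± 0.16). Of the heat shock genes 3 of 7 rose over all transcripts, 3 adjusted over the list alone, and 7 were above 0 (adjusted p = 0.0112, and adjusted p = 0.483 with an estimated correlation). Hsp90aa1 stood at 1.09 ± 0.25, uncertain because Hsp90ab1 is closely similar, Hspd1 at 0.82 ± 0.17 and Hsph1 at 0.77 ± 0.19. All 40 ribosomal protein and elongation factor genes were above 0, 3 rose over all and 1 adjusted over the list alone (adjusted p = 2.06e-04, and adjusted p = 0.513 with an estimated correlation). These were Rpl27 (0.71 ± 0.17), Rps7 (0.61 ± 0.18) and Rps6 (0.64 ± 0.19), read with the same caution about pseudogenes. The amino acid lists did not pass (adjusted p = 0.938 for transporters, 0.938 for synthesis and 0.366 for synthetases). Aldh18a1 fell (-1.10 ± 0.26), and Atf4 stood at 0.16 ± 0.19. The cyclin gene Ccnd1 rose (1.05 ± 0.29). With NT in place of NT2 as the control the chaperone median turned to 0.16 (adjusted p = 0.344), and the NRF2 (0.0595), heat shock (0.0589) and matrix (0.534) lists did not pass. With both untreated groups as the control the chaperone list did not pass (0.359). Of 35 called named genes 20 were not called with NT as the control, and 12 turned direction, namely Lca5l (-1.30), Lrp2bp (-1.19), Kifc2 (-2.09), Pcdha9 (-3.56), Clu (-1.41), Slc6a15 (-4.45), Lrrn4 (0.32), Vsig8 (0.086), Pdia4 (0.26), Pdia6 (0.061), Calr (0.31) and Lox (0.072). Of these Kifc2, Pcdha9, Clu and Slc6a15 were then called lower.

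Large rises were in the tracking transcripts Lca5l (2.42 ± 0.64), Lrp2bp (5.2-fold, 95% interval 1.45 to 28.2), the xanthine dehydrogenase gene Xdh (2.04 ± 0.56), Kifc2 (1.92 ± 0.50), Pcdha9 (1.83 ± 0.49), the clusterin gene Clu (1.80 ± 0.32) and the transporter gene Slc6a15 (1.78 ± 0.41). Large falls were in Plekha6 (-2.22 ± 0.49), Plxna4, a semaphorin receptor gene (-1.88 ± 0.21), Lrrn4 (-1.59 ± 0.20), Heg1 (-1.52 ± 0.20), the ubiquitin ligase gene Rnf213 (-1.51 ± 0.21), the neutral sphingomyelinase gene Smpd3 (-1.49 ± 0.22) and Vsig8 (-1.48 ± 0.22), none of them tracking. By edgeR's quasi-likelihood test 77 transcripts were higher, 23 of them tracking, and 70 lower. Without the tracking transcripts it called 168 and 159. DESeq2 called 96 and 67, and limma called 0 (387 had an unadjusted p under 0.05 by edgeR). With only the second experiment fitted, edgeR called 375 against 147. The count was 32 without NT2 replicate 1, 27 without NT2 replicate 2, 22 without cysteamine replicate 1 and 15 without cysteamine replicate 2. In that order 18, 23, 23 and 25 of the 35 called named genes were not called there. The 9 called in every such fit were Clu, Col6a2, Heg1, Lrrn4, Pdia4, Plxna4, Rnf213, Smpd3 and Vsig8. The higher share of calls was 52.4%, 62.5% after quantile normalization, which moved the median over all transcripts from 0.13 to 0.01.

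CTNS knockdown against NT2 asks what loss of cystinosin changes; the level of Ctns itself is not analysed here, so the knockdown was not checked at its target. Of 20 extracellular matrix genes 16 fell, and the call of the list did not hold with an estimated correlation (adjusted p = 0.0585). Lox measured 133 ± 46.1 CPM in the knockdown against 974 ± 5.54 CPM in NT2 (log2 fold change -2.83 ± 0.21, adjusted p = 7.10e-07). Col1a2 measured 843 ± 73.6 against 6024 ± 714 CPM (-2.84 ± 0.35), and the matricellular gene Thbs1 150.0 ± 20.4 against 807 ± 11.9 CPM (-2.43 ± 0.23). Of the matrix genes 1, the tracking transcript P4ha1, rose (1.31 ± 0.33). Adjusted over the list alone 17 fell and 1 rose, with a median of -1.56 (adjusted p = 2.84e-13 with the preset correlation). Sqstm1 rose from 324 ± 61.8 to 1546 ± 34.8 CPM (2.24 ± 0.24, adjusted p = 2.20e-05).

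Further matrix and basement membrane genes that fell were Col5a2 (-2.49 ± 0.28) and the nidogen gene Nid2 (-2.43 ± 0.21). Lrrn4 (-2.71 ± 0.25), the lymphatic growth factor receptor gene Flt4 (-2.40 ± 0.45) and Smpd3 (-2.35 ± 0.27) were the other transcripts among the 8 lowest. Of 11 contractile genes and YAP targets 5 fell, 6 adjusted over the list alone, and 10 were below 0 (adjusted p = 0.00998, and adjusted p = 0.663 with an estimated correlation; adjusted p = 0.0718 without the tracking transcripts). Those that fell included the focal adhesion gene Vcl (-1.28 ± 0.23), Acta2 (-0.92 ± 0.20), Tagln (-1.35 ± 0.31) and Tpm1 (-0.90 ± 0.21). Of 40 ribosomal protein and elongation factor genes 37 were below 0, 5 fell over all and 2 adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.864 with an estimated correlation; adjusted p = 0.24 without the tracking transcripts). Rpl12 (-0.94 ± 0.22) and Rpl7 (-0.86 ± 0.21) fell, again uncertain. In lists that did not pass as a whole, Hsph1 (1.002 ± 0.20), Hsp90aa1 (0.97 ± 0.25), Sars (0.85 ± 0.25), the folliculin-interacting gene Fnip2, tracking (0.88 ± 0.31), and the centromere gene Cenpf (0.82 ± 0.21) rose. The lysosomal protease gene Ctsl (-0.68 ± 0.23), Rrm1, a ribonucleotide reductase gene (-0.96 ± 0.21), the glycolytic genes Gapdh (-1.03 ± 0.24) and Eno1 (-0.70 ± 0.22), and Slc38a2 (-0.73 ± 0.24), Aldh18a1 (-1.04 ± 0.29) and Vars (-0.75 ± 0.23) fell. Gapdh has many pseudogenes and is uncertain. Atf4 stood at -0.36 ± 0.21 (adjusted p = 0.213), and the 3 NRF2 targets did not pass (adjusted p = 0.993 for the list). With NT in place of NT2 as the control the matrix list still passed, with a median of -0.98 (adjusted p = 1.15e-04), and the ribosomal median turned to 0.45, while the contractile list did not pass (0.767). With both untreated groups as the control the ribosomal (0.327) and contractile (0.0924) lists did not pass. Neither passed after quantile normalization (0.0656 and 0.0527) or with a mean count of 20 or more (0.0551 and 0.0551). Of 38 called named genes 31 were not called with NT as the control, and the 7 that were are Lox, Col1a2, Col5a2, Thbs1, Smpd3, Sqstm1 and Hsp90aa1. Among the others 12 turned direction, including Ctrb1 (-0.59), Adam33 (-1.42), Nme9 (-1.71), Slc38a2 (0.30), Fnip2 (-0.83), Rrm1 (0.011), Rpl7 (0.19), Acta2 (0.72), P4ha1 (-1.14) and Eno1 (0.14).

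The 8 largest rises were all in tracking transcripts, namely Ctrb1 (298 ± 69.6 against 13.2 ± 1.87 CPM; 4.38 ± 0.59), Lca5l (3.91 ± 0.58), Mall (3.73 ± 0.68), Aatk (3.68 ± 1.18), the metalloprotease gene Adam33 (13.3-fold, 95% interval 3.96 to 69.5), Nme9 (3.43 ± 0.67), the peroxisomal oxidase gene Acox3 (3.39 ± 0.47) and Cbfa2t3 (3.38 ± 0.83). The epithelial marker Cdh1 (2.39 ± 0.73, adjusted p = 0.0218) and the muscle marker Ttn (1.60 ± 0.30, adjusted p = 0.00118) rose with them. The test called 246 transcripts higher, 167 of them tracking, and 185 lower, 0 of them tracking. Without the tracking transcripts it called 172 and 198. DESeq2 called 229 and 157, and limma 94 and 37, which moved the higher share from 57.1% to 71.8%. Quantile normalization moved the median over all transcripts from 0.09 to -0.06. The count was 191 and 231 without NT2 replicates 1 and 2, and 237 and 231 without knockdown replicates 1 and 2, against 431 with all libraries. In that order 18, 9, 11 and 13 of the 38 called named genes were not called there. Lox, Col1a2, Col5a2, Nid2, Thbs1, Lrrn4, Flt4, Smpd3, Vcl, Acta2, Sqstm1 and 6 of the tracking transcripts were called in every such fit.

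**Figure D3:**
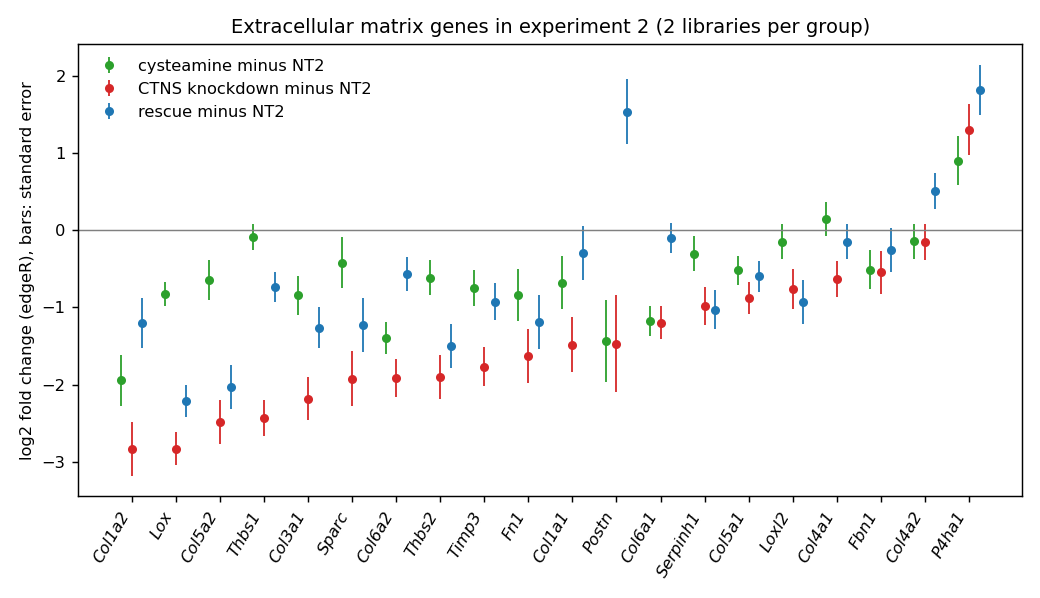
Log2 fold changes against NT2 (points) with their standard errors (bars) for 20 extracellular matrix genes with cysteamine (green), in the CTNS knockdown (red) and in the rescue (blue). Lox lay at -2.83 in the knockdown and -2.21 in the rescue, and the tracking transcripts P4ha1 and, in the rescue, Postn lay above the other genes.

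Rescue against CTNS knockdown asks which knockdown changes are undone when CTNS is supplied from a plasmid. Of 20 extracellular matrix genes 5 rose, and the call of the list did not hold with an estimated correlation (adjusted p = 0.0848). Thbs1 measured 476 ± 131 CPM in the rescue against 150.0 ± 20.4 CPM in the knockdown (log2 fold change 1.69 ± 0.27), and Col1a2 2608 ± 535 against 843 ± 73.6 CPM (1.63 ± 0.34). Col6a2 rose by 1.35 ± 0.29, Col6a1 by 1.10 ± 0.23 and Postn, tracking, by 3.01 ± 0.58. Adjusted over the list alone 9 rose, 18 were above 0 and the median was 0.64 (adjusted p = 1.48e-11 with the preset correlation). Also higher were Rnf213 (2.07 ± 0.21, adjusted p = 6.27e-05), Acta2 (1.23 ± 0.21), Ccdc80, a matrix-associated gene (1.66 ± 0.36), and the macrophage growth factor gene Csf1 (1.23 ± 0.26). These 9 were called by edgeR's quasi-likelihood test on all 14 libraries, with 0 lower. Without the tracking transcripts it called 28 higher and 7 lower. With only the second experiment fitted it called 58, 41 higher and 17 lower. An unadjusted p under 0.05 was found for 154, DESeq2 called 10 higher and 4 lower, so 71.4% higher against 100% here, and limma 1 and 0. Of the 9, 8 had been called lower in the knockdown, the exception being Postn.

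The count was 4 without knockdown replicate 1, 1 without knockdown replicate 2, 2 without rescue replicate 1 and 3 without rescue replicate 2. Of the 9 calls 6, 8, 7 and 6 were lost, Rnf213 alone was called each time, and the matrix list passed each time. Of 11 contractile genes 1 rose over all, 1 adjusted over the list alone, and 10 were above 0 (adjusted p = 0.0475, and adjusted p = 0.358 with an estimated correlation). All 7 heat shock genes were below 0, with 0 calls over all and 1 adjusted over the list alone (adjusted p = 0.0475, and adjusted p = 0.416 with an estimated correlation). Of 40 ribosomal protein genes 30 were below 0, with 0 calls over all and 0 adjusted over the list alone (adjusted p = 0.0475, and adjusted p = 0.655 with an estimated correlation). These 3 lists passed in no fit that left out a library of the comparison (adjusted p from 0.061 to 0.146), nor by limma on log2 CPM values (0.0593 for ribosomal proteins, 0.0557 for heat shock and 0.0557 for contractile genes). The ribosomal (0.201) and heat shock (0.0585) lists did not pass without the tracking transcripts. Hsp90aa1 stood at -0.81 ± 0.26, Rps7 at -0.73 ± 0.23, Sqstm1 at -0.49 ± 0.24 and Lox at 0.62 ± 0.30 (adjusted p = 0.451). Over the 185 transcripts called lower in the knockdown, 136 (73.5%) were higher in the rescue than in the knockdown, and in 100 simulations of groups without difference 62.4% on average and 71.4% at most were. Both comparisons use the knockdown libraries, which raises this share with no effect at all. Of 79 other transcripts called higher, 61 (77.2%) were lower in the rescue, no more than the highest simulated share (64.8% on average and 77.2% at most). Their median difference of mean log2 CPM was -0.219, and -0.201 at the lowest in the simulations. For the 185 called lower it was 0.217, and 0.141 at the highest in the simulations. Of 167 tracking transcripts called higher, 24 (14.4%) were lower in the rescue (simulated 53.6% on average and 61.7% at most).

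Rescue against NT2 asks what still differed from untreated cells. Of 20 extracellular matrix genes 12 fell and 2 rose, and the call of the list did not hold with an estimated correlation (adjusted p = 0.699). Lox measured 209.5 ± 1.44 CPM against 974 ± 5.54 CPM in NT2 (log2 fold change -2.21 ± 0.21, adjusted p = 9.32e-06). Col5a2 stood at -2.03 ± 0.28, Nid2 at -1.81 ± 0.20 and Thbs2 at -1.50 ± 0.29. Adjusted over the list alone 13 fell and 2 rose (adjusted p = 6.28e-04 with the preset correlation). Of 40 ribosomal protein and elongation factor genes 16 fell, 19 adjusted over the list alone, and 35 were below 0 (adjusted p = 2.46e-04, and adjusted p = 0.699 with an estimated correlation). Rpl12 stood at -1.34 ± 0.24, Rpl15 at -1.04 ± 0.22 and the elongation factor gene Eef1b2 at -0.83 ± 0.23, uncertain as before. Sqstm1 (1.75 ± 0.26), Abcc1 (1.13 ± 0.29), Vegfa (1.30 ± 0.26), Ccnd1 (1.001 ± 0.32) and Hsph1 (0.77 ± 0.21) rose. Atf4 fell (-0.91 ± 0.24, adjusted p = 0.00908). With NT as the control the matrix list did not pass (adjusted p = 0.275) and the ribosomal median turned to 0.32; with both untreated groups the ribosomal list did not pass (0.901). Of 39 called named genes 33 were not called with NT as the control, and 10 turned direction: Ctrb1 (-0.089), Nme9 (-0.94), Fgl1 (-0.49), Fnip2 (-0.71), Rrm1 (0.020), Pdia4 (0.59), Pdia3 (0.36), P4ha1 (-0.63), Tpm1 (0.0030) and mt-Nd2 (0.59).

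Also lower were the semaphorin gene Sema3d (-2.45 ± 0.69), Lrrn4 (-2.14 ± 0.25), Strap (-2.13 ± 0.37), the helicase gene Blm (3.92-fold lower, 95% interval 1.22 to 20.1), Vcl (-1.002 ± 0.23) and Tpm1 (-0.72 ± 0.21). The same held for Pdia4 (-0.98 ± 0.23), Pdia3 (-0.84 ± 0.20), the mitotic kinase gene Aurkb (-1.26 ± 0.44), Rrm1 (-0.95 ± 0.22), Gapdh (-0.81 ± 0.25), mt-Nd3 (-1.19 ± 0.35), mt-Nd2 (-0.64 ± 0.21) and Hspa4 (-0.61 ± 0.22). The 8 highest were tracking. They were Ctrb1 (4.88 ± 0.58), Gpr162 (25.5-fold, 95% interval 7.95 to 130.2), Lca5l (4.40 ± 0.57) and Mall (4.35 ± 0.65). Next came Nyap2 (23.0-fold, 95% interval 7.11 to 118), Nme9 (4.20 ± 0.63), Aatk (4.11 ± 1.18) and Fgl1 (19.7-fold, 95% interval 5.99 to 102). P4ha1 (1.82 ± 0.33) and Fnip2 (1.01 ± 0.32), also tracking, rose. The test called 261 transcripts higher, 59 of them not tracking, and 180 lower, 1 of them tracking. Leaving the tracking transcripts out gave 136 and 151. DESeq2 called 247 and 154, and limma 146 and 22. The higher share was 59.2%, 86.9% by limma and 70.0% after quantile normalization, which moved the median over all transcripts from -0.01 to -0.19. Leaving out a library gave 257, 271, 287 and 266 calls (NT2 replicate 1, rescue replicate 1, NT2 replicate 2, rescue replicate 2) against 441 with all libraries. In that order 16, 12, 9 and 17 of the 39 called named genes were not called.

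Across comparisons, some transcripts were called in the same direction with cysteamine and in the knockdown. Their log2 fold changes correlated at r = 0.634 over 1399 transcripts and 0.446 over the 1058 others, which are not independent observations. In comparison, 100 simulations of unchanged groups against shared untreated libraries gave 0.423 and, over the others, 0.426, close to the value found, and the covariance was 0.299 against a simulated 0.031 (over the others 0.134 against 0.0238). Both rose in 31 transcripts and both fell in 39, where independent lists give 13.5 and 9.26. Without the tracking transcripts the numbers were 38 and 82 against 27.3 and 29.8. Lox, Col1a2, Lrrn4, Smpd3 and Aldh18a1 fell in both, and Sqstm1, Hsp90aa1, Hsph1 and Lca5l rose in both. For knockdown and rescue, each against NT2, r was 0.893 (simulated 0.353; covariance 0.786 against 0.0320), and 0.770 over the others (simulated 0.358). Of the transcripts 194 rose in both and 116 fell in both (45.9 and 23.8 for independent lists). Part of each excess may come from the shared NT2 libraries, which were not split because each part would hold 1 library. Cysteine starvation and full amino acid starvation, which share NT, correlated at 0.128 (simulated 0.637; covariance 0.0772 against 0.505), and at 0.441 over the others (simulated 0.643). Cysteine starvation shares no library with the second experiment. It correlated at -0.240 with cysteamine and -0.499 with the knockdown over all transcripts, and at 0.0779 and -0.0951 over the others. Leaving out full amino acid starvation replicate 2 turned the correlation of the starvations to -0.0223.

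The effects of cysteamine and of cysteine starvation, each against its own untreated group, differed in some amino acid genes. The difference was negative, that is lower for cysteamine, in Mthfd2 (-2.72 ± 0.69), Lars (-2.50 ± 0.64), Aldh18a1 (-2.35 ± 0.56), Aars (-2.07 ± 0.42), Col1a2 (-2.57 ± 0.48), Lox (-1.87 ± 0.33), Acta2 (-1.88 ± 0.45) and Fam129a (-2.68 ± 0.65). It was positive in the tracking transcripts Ctrb1 (4.81 ± 1.08), Pla2g4f (4.15 ± 1.17), Robo1 (4.12 ± 1.13), Lca5l (4.05 ± 1.12) and Nme9 (3.84 ± 1.01). In all 62 were positive, 61 of them tracking, and 33 negative (309 with an unadjusted p under 0.05; DESeq2 91 and 36, limma 26 and 7). These were 3 and 18 without the tracking transcripts. The higher share was 65.3%, 78.8% by limma and 55.0% after quantile normalization, which moved the median over all transcripts from 0.094 to -0.030. The count was 153 and 20 without NT replicates 1 and 2, 8 and 100 without cysteine starvation replicates 1 and 2, 0 without either NT2 library, and 0 and 25 without cysteamine replicates 1 and 2. In that order 8, 13, 13, 4, 17, 17, 17 and 11 of the 17 called named genes were lost. Amino acid synthesis (adjusted p = 0.0408), synthetases (0.00224), endoplasmic reticulum chaperones (0.00131) and extracellular matrix (4.52e-06) passed as lists, synthesis in no fit without NT replicate 1 (0.0556), cysteine starvation replicate 2 (0.104) or NT2 replicate 2 (0.0583). Synthesis did not pass after quantile normalization (0.053) or without the tracking transcripts (0.0626). With an estimated correlation the adjusted p was 0.175, 0.175, 0.189 and 0.175.

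The knockdown effect differed from that of cysteine starvation in the same direction for some matrix and amino acid genes. The difference was -3.88 ± 0.36 for Lox, -3.47 ± 0.49 for Col1a2, -3.38 ± 0.41 for Col5a2, -3.09 ± 0.40 for Thbs1, -3.39 ± 0.54 for Lrrn4, -3.26 ± 0.40 for the monoamine transporter gene Slc18a2, -2.98 ± 0.70 for Mthfd2, -1.90 ± 0.53 for Slc38a2 and -1.49 ± 0.42 for Atf4 (adjusted p = 0.0204). It was positive in Ctrb1 (7.02 ± 1.04), Adam33 (5.73 ± 1.10), Lca5l (5.53 ± 1.13), Nme9 (5.36 ± 0.97) and Pla2g4f (5.04 ± 1.16), all tracking. Of the calls 168 were positive, 165 of them tracking, and 100 negative (463 with an unadjusted p under 0.05; DESeq2 192 and 83, limma 156 and 71). They were 6 and 45 without the tracking transcripts. Synthesis (adjusted p = 0.0188; 0.181 with an estimated correlation), ribosomal proteins (1.97e-06; 0.357), extracellular matrix (1.25e-08; 0.177) and contractile genes (0.005; 0.298) passed as lists. Among transcripts with a mean count of 20 or more the synthesis (0.0679) and contractile (0.0519) lists did not. Quantile normalization moved the median over all transcripts from -0.021 to -0.20. Of 30 called named genes 13 were called in every leave-out fit, and 8 and 11 were lost without NT replicates 1 and 2, 11 and 2 without cysteine starvation replicates 1 and 2, 9 and 3 without NT2 replicates 1 and 2, and 4 and 9 without knockdown replicates 1 and 2.

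Between knockdown and cysteamine, which share NT2, lower in the knockdown were the nidogen gene Nid1 (219 ± 64.8 against 1409 ± 128 CPM; -2.70 ± 0.21), S100a4 (-2.53 ± 0.57), Thbs1 (-2.35 ± 0.24), the kinase gene Nuak1 (-2.10 ± 0.42), Lox (-2.01 ± 0.23) and Prdx1 (-1.42 ± 0.21). Higher were the chaperone gene Hspa5 (1.45 ± 0.28), Sqstm1 (1.02 ± 0.23) and the tracking transcripts 4930544D05Rik (10.2-fold, 95% interval 2.27 to 93.9), Adam33 (3.01 ± 0.68), Slc17a9 (8.51-fold, 95% interval 1.81 to 79.9), Recql5 (2.28 ± 0.52) and Ctrb1 (2.21 ± 0.47). In total 141 were higher, 71 of them tracking, and 205 lower (531 with an unadjusted p under 0.05; DESeq2 103 and 180, limma 0 and 4). Without the tracking transcripts the numbers were 167 and 220, and with only the second experiment fitted 529 were called against 346. The count was 127 and 67 without cysteamine replicates 1 and 2, and 117 without either knockdown library, with 19, 25, 20 and 22 of 42 called named genes lost. Every such fit called 11 of them. The NRF2 list (2 of 3 fell; adjusted p = 0.00881, and adjusted p = 0.154 with an estimated correlation) and ribosomal proteins (29 of 40 fell; adjusted p = 1.14e-11, and adjusted p = 0.203 with an estimated correlation) passed, both lower in the knockdown. Extracellular matrix (8 of 20 fell; adjusted p = 4.30e-07, and adjusted p = 0.154 with an estimated correlation) and contractile genes (7 of 11 fell; adjusted p = 3.49e-04, and adjusted p = 0.191 with an estimated correlation) were lower too. Endoplasmic reticulum chaperones were higher in the knockdown (4 of 8 rose; adjusted p = 0.0219, and adjusted p = 0.298 with an estimated correlation), but not without knockdown replicate 2 (adjusted p = 0.0771). The higher share was 40.8%, 0% by limma and 69.2% after quantile normalization.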

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

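The tests of the tracking transcripts' makeup and of a knockdown response, of the matrix genes, and of the tracking share behind the amino acid genes were chosen after the result was seen; the tests of shared reads and of NT replicate 2 were written before theirs. 3 differences between effects were picked out because the test of the difference itself found transcripts past the threshold. The cysteamine and cysteine starvation effects differed in 95 transcripts, the knockdown and cysteine starvation effects in 268, and the knockdown and cysteamine effects in 346. Without the tracking transcripts these numbers were 21, 51 and 387. No group had enough libraries to look for a library far from the others.

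The tracking transcripts moved as a class, though not every member did. Their median log2 fold change was -1.76 in cysteine starvation against full amino acid starvation and 1.32 in knockdown against NT2. The first comparison uses no library of the definition, while the second uses NT2, which favours a rise. A response to the knockdown as the whole cause is argued against by the untreated groups, whose tracking share differed by 7.94 times; the class was defined from that ratio, but the 3 dominant transcripts, picked by total count alone, also took 45.3% in NT and 3.39% in NT2. Reads shared with the dominant transcripts are argued against because 11.4% of 333 tracking transcripts (Wilson 95% interval 8.43 to 15.3%) hold a stretch of 20 bases of them, so 295 hold none; this criterion was added later, and the ratio to transcripts of matched length, 1.41 (0.880 to 2.25), which the earlier criterion used, left the matter undecided. A component of constant makeup whose share differs between libraries, such as carried-over nucleic acid or unspecific alignments, cannot be told apart from other sources: the correlation of -0.602 across transcripts between those comparisons follows from the class moving in opposite directions, and the -0.465 within the class and -0.200 among the others were set against no value expected without it. What the component is stays open. Experiment as the only source of its share is argued against by the second experiment. There the tracking share ran from 16.8% ± 0.807 with cysteamine to 40.6% ± 1.71 in the rescue, both groups outside the definition. Whether experiment or batch adds to the share stays open, since the untreated groups differ by experiment alone as far as the labels state.

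Of 20 extracellular matrix genes 16 fell in the knockdown against NT2, and 5 rose in the rescue against the knockdown. An effect of the differing tracking share through the scaling is argued against. The median of the list in knockdown against NT2 was -1.58 with the tracking transcripts left out and -1.56 with them. Counts that their source may add to the other matrix genes stayed in that fit, so it cannot decide on such added counts. Chance values of the shared knockdown libraries cannot be told apart from a return. The list in rescue against knockdown passed with the preset correlation and not with an estimated one (adjusted p = 0.0848). Of the list 90% was higher in the rescue, against 75% at most in 100 simulations without a difference. The median difference of mean log2 CPM, not the fitted fold change below, was 0.632 against 0.160 at most. These simulations cannot decide the matter. On average 49.5% of the list was higher in them, against 62.4% of the transcripts called lower in the knockdown, so a list lying low by chance was not simulated. They also let each gene vary independently, which these genes need not do. An effect of the hairpin vector other than loss of Ctns cannot be told apart either: the median in rescue against knockdown was 0.641, but the rescue stayed below NT2, no control hairpin group was analysed here, and neither was Ctns. That supply of CTNS restores matrix genes is thus a hypothesis these libraries leave open.

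Amino acid transporter, synthesis and synthetase genes lay higher in cysteine starvation than in NT, with a median log2 fold change of 1.11 over 17 genes. The poorer library NT replicate 2 is argued against as the cause, because without it the median was 0.918 and 16 of 17 were above 0. An effect of the tracking share through the scaling is argued against, because the median was 0.911 with these transcripts left out, 14 of 16 above 0. Counts that the source of the tracking transcripts may add to the amino acid genes themselves stayed in that fit. Leaving the tracking transcripts out therefore cannot decide on such added counts. A response to amino acid shortage, in which Atf4 drives such genes, may underlie the pattern and is the explanation the design offers. It was found and examined on the same libraries, and no list call held with an estimated correlation, so it remains a hypothesis. In full amino acid starvation against NT, Atf4 stood at 0.021 ± 0.49, and the synthetases were the only list to pass with the preset correlation. The median of the 17 genes was 1.03 there, with 13 above 0. The thin counts of NT, 3 for Slc3a2, and the assignment of NT as the control stay open: with NT2 as the control the transporter list did not pass (adjusted p = 0.262).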

How the results depend on the processing

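Settings without the tracking transcripts, with them defined from the rescue libraries, and with a mean count of 20 or more were chosen after the data were seen, as was limma on log2(CPM + 1) beside edgeR. For single named transcripts, settings other than a left-out library kept 6930 values on the same side of the threshold. They gave 972 weaker, 364 newly past the threshold and 37 reversed. Leaving out a library gave 2626, 531, 51 and 0. For lists the numbers were 1623, 93, 38 and 6, and 671, 28, 21 and 0. A reversal was counted only for a call of the main test, so other values could turn direction uncounted. Aldh18a1 with cysteine starvation, for example, stood at 1.25 and at -0.035 without NT replicate 1. Below, a count is of transcripts past the threshold, to be read against these values of the main test. They are 0 for cysteine starvation, 0 for full starvation, 210 for cysteine against full starvation, 147 for cysteamine and 431 for knockdown. They are also 9 for rescue against knockdown, 441 for rescue against NT2 and 95 for cysteamine minus starvation effect. The last are 268 for knockdown minus starvation effect and 346 for knockdown minus cysteamine effect. List calls are to be read against 35 over all comparisons and differences, 22 of them in the comparisons of groups alone. A call lost with a left-out library may reflect fewer libraries. For other changes, such as calls gained for cysteine starvation without NT replicate 1, the cause was not tested. Low counts in the first experiment limit its comparisons, with a median count of 3 in its thinnest library. CPM filters at 1, 5 and 20 and the restriction to transcripts seen in every library removed 0 transcripts and test nothing, edgeR on recovered reads is the test used, and alternatives on Ctns gave no value.

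Counts and correlations that moved were these. With DESeq2 the values were 60 for cysteine starvation, 14 for rescue against knockdown. With median-of-ratios scaling the values were 2 for cysteine starvation. With limma on log2(CPM + 0.25) the values were 5 for cysteine starvation, 13 for full starvation, 0 for cysteamine, 134 for knockdown, 1 for rescue against knockdown, 168 for rescue against NT2, 33 for cysteamine minus starvation effect, 4 for knockdown minus cysteamine effect. On log2(CPM + 1) the values were 5 for cysteine starvation, 13 for full starvation, 0 for cysteamine, 131 for knockdown, 1 for rescue against knockdown, 168 for rescue against NT2, 33 for cysteamine minus starvation effect, 4 for knockdown minus cysteamine effect. On log2(CPM + 5) the values were 5 for cysteine starvation, 13 for full starvation, 0 for cysteamine, 126 for knockdown, 1 for rescue against knockdown, 163 for rescue against NT2, 33 for cysteamine minus starvation effect, 4 for knockdown minus cysteamine effect. With limma without trend the values were 0 for cysteamine, 122 for knockdown, 1 for rescue against knockdown, 153 for rescue against NT2, 0 for cysteamine minus starvation effect, 4 for knockdown minus cysteamine effect. After quantile normalization the values were 4 for cysteine starvation, 16 for cysteamine, 127 for knockdown, 3 for rescue against knockdown, 150 for rescue against NT2, 20 for cysteamine minus starvation effect, 39 for knockdown minus cysteamine effect, -0.12 for the correlation of starvation and cysteamine, -0.308 for the correlation of starvation and knockdown. With libraries of 1 experiment only the values were 87 for cysteine against full starvation, 375 for cysteamine, 58 for rescue against knockdown, 529 for knockdown minus cysteamine effect. With an estimated correlation the values were 0 for list tests passed. With a mean count of 20 or more the values were 117 for cysteine against full starvation. List calls that did not pass numbered 4 by limma with each of the pseudocounts 0.25, 1 and 5, 3 after quantile normalization and 8 with a mean count of 20 or more; the contractile list of cysteine against full starvation stood at adjusted p 0.0532 to 0.0552 over the pseudocounts.

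Without the tracking transcripts the values were 18 for cysteine against full starvation, 327 for cysteamine, 35 for rescue against knockdown, 287 for rescue against NT2, 21 for cysteamine minus starvation effect, 51 for knockdown minus starvation effect, -0.0951 for the correlation of starvation and knockdown, 0.441 for the correlation of starvation and full starvation, 0.446 for the correlation of cysteamine and knockdown. With tracking transcripts defined from the rescue the values were 8 for cysteine starvation, 1 for full starvation, 49 for cysteine against full starvation, 301 for cysteamine, 20 for rescue against knockdown, 237 for rescue against NT2, 33 for cysteamine minus starvation effect, 93 for knockdown minus starvation effect, -0.192 for the correlation of starvation and knockdown, 0.372 for the correlation of starvation and full starvation, 0.413 for the correlation of cysteamine and knockdown. With tracking transcripts defined from the rescue, 7 list calls did not pass, as in the first definition: 0.0934, 0.11, 0.057 for the contractile list with cysteine starvation, in cysteine against full starvation and in the knockdown, 0.147 for ribosomal proteins in the knockdown, 0.272 and 0.0887 for ribosomal proteins and heat shock in rescue against knockdown, and 0.0612 for synthesis in the cysteamine minus starvation effect. The correlation of starvation and cysteamine turned from -0.240 to 0.0779 and 0.0562 under these settings, where by construction fewer transcripts enter.

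With the other untreated group as control the values were 248 for cysteine starvation, 459 for full starvation, 356 for cysteamine, 203 for knockdown, 155 for rescue against NT2. With both untreated groups as control the values were 8 for cysteine starvation, 249 for full starvation, 249 for cysteamine, 128 for knockdown, 107 for rescue against NT2. The untreated groups differ in makeup, so the exchange also carries that difference. With the other group, log2 fold changes that turned for cysteamine were Lca5l -1.30, Lrp2bp -1.19, Kifc2 -2.09, Pcdha9 -3.56, Clu -1.41, Slc6a15 -4.45, Lrrn4 0.32, Vsig8 0.086, Pdia4 0.26, Pdia6 0.061, Calr 0.31, Lox 0.072, the endoplasmic reticulum chaperone list 0.16. For knockdown they were Ctrb1 -0.59, Adam33 -1.42, Nme9 -1.71, Slc38a2 0.30, Fnip2 -0.83, Rrm1 0.011, Rpl7 0.19, Rpl7a 0.25, Rps16 0.11, Acta2 0.72, P4ha1 -1.14, Eno1 0.14, the ribosomal protein list 0.45. For rescue against NT2 they were Ctrb1 -0.089, Nme9 -0.94, Fgl1 -0.49, Fnip2 -0.71, Rrm1 0.020, Pdia4 0.59, Pdia3 0.36, P4ha1 -0.63, Tpm1 0.0030, mt-Nd2 0.59, the ribosomal protein list 0.32. For cysteine starvation, list medians turned to the ribosomal protein list -0.27, the contractile list -0.028. With both groups, those that turned were Kifc2 -0.086, Pcdha9 -0.87, Slc6a15 -1.33 for cysteamine and the ribosomal protein list 0.031 for knockdown; the cause was not tested.

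The labels do not say that replicate numbers pair the libraries, and 2 per group are too few for the data to show it: same-numbered libraries' deviations correlated at 0.287 between NT and cysteine starvation, -0.214 between NT and full starvation and -0.0575 between the starvations, and at 0.0920 to 0.281, all 6 above 0, in the second experiment. With the block the values were 80 for cysteine starvation, 269 for cysteamine, 143 for cysteamine minus starvation effect. The block moved no other count by over 1.5 times, and 5 list calls did not pass with it: the synthetase list of full starvation (adjusted p = 0.0619), the contractile list of cysteine against full starvation (0.069), and the ribosomal protein, heat shock and contractile lists of rescue against knockdown (0.0601 each). The transporter list of the cysteamine minus starvation effect passed with it (0.0332).

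With each library left out in turn the ranges were 0 to 112 for cysteine starvation, 0 to 20 for full starvation, 18 to 193 for cysteine against full starvation, 15 to 32 for cysteamine, 191 to 237 for knockdown, 1 to 4 for rescue against knockdown. They were also 257 to 287 for rescue against NT2, 0 to 153 for cysteamine minus starvation effect, 67 to 127 for knockdown minus cysteamine effect, -0.524 to -0.265 for the correlation of starvation and knockdown, -0.0223 to 0.576 for the correlation of starvation and full starvation. The value of -0.0223 came without full amino acid starvation replicate 2, and the cause was not tested.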

Other observations

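All values here were looked up after the main results were seen, apart from the lists, which were fixed earlier. 6 lists passed in none of the 7 comparisons. Of the 7 lysosomal genes measured, Sqstm1 rose with cysteamine (1.21 ± 0.25), in the knockdown (2.24 ± 0.24) and in the rescue (1.75 ± 0.26), Fnip2, tracking, rose in the knockdown and the rescue (1.01 ± 0.32 in the latter), Ctsl fell in the knockdown (-0.68 ± 0.23), and the lysosomal membrane gene Lamp1 stood between -0.38 in the rescue and 0.66 with cysteine starvation (adjusted p for the list 0.533 to 0.938). Of 13 cell cycle genes, Rrm1 fell in the knockdown (-0.96 ± 0.21) while Cenpf rose (0.82 ± 0.21), and Ccnd1 rose with cysteamine (1.05 ± 0.29); the proliferation marker Mki67 stood at -0.98 ± 0.47 with cysteine starvation and the replication gene Mcm3 at 1.82 ± 0.63 (3.54-fold, 95% interval 1.09 to 18.2; list adjusted p 0.0822 to 0.87). Of 11 proteasome genes Psmd3 stood at 1.74 ± 0.59 between the starvations and Psmd11 at 0.77 ± 0.29 in the knockdown (list adjusted p 0.0815 to 0.997). Of 7 glycolysis and hypoxia genes Gapdh fell in the knockdown (-1.03 ± 0.24) and Vegfa rose in the rescue (1.30 ± 0.26; list adjusted p 0.065 to 0.87). Of 7 mitochondrially encoded genes mt-Nd3 (-1.19 ± 0.35) and mt-Nd2 (-0.64 ± 0.21) fell in the rescue against NT2 and mt-Nd1 rose in cysteine against full starvation (1.46 ± 0.44; list adjusted p 0.119 to 0.938). Of 5 ferroptosis genes all were above 0 with cysteine starvation (adjusted p = 0.0738; 0.0651 to 0.87 over the comparisons); they share Slc3a2 and Fth1 with other lists.

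Lists with fewer than 3 measured members were not tested as lists. Gpx4, the peroxidase that restrains ferroptosis, stood at 1.26 ± 0.76 (2.47-fold, 95% interval 0.558 to 22.5) with cysteine starvation and 0.026 ± 0.28 in the knockdown. Srebf2, a regulator of cholesterol synthesis, lay between -0.36 and 0.22 in the 7 comparisons, and Fdft1 of the same pathway, tracking, fell in cysteine against full starvation (-1.70 ± 0.53). The immediate early gene Srf stood at -0.42 ± 0.67 with cysteine starvation and -0.72 ± 0.39 in the knockdown. The epithelial marker Cdh1 and the muscle marker Ttn, both tracking, stood at 1.61 ± 0.88 and 2.17 ± 0.29 in rescue against NT2, and at -0.77 ± 0.72 and 0.57 ± 0.27 in rescue against knockdown. Of the targets of the aryl hydrocarbon receptor and of p53, metallothioneins, interferon response genes, and macrophage or leukocyte, endothelial and neural markers, 0 were among the transcripts analysed here.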
